A study of Mus musculus with 18 samples.

How the data were processed

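Bulk RNA sequencing was done on prefrontal cortex and hippocampus from male mice, with total RNA taken up in Trizol, libraries made with the VAHTS Universal V5 RNA kit and sequencing on a NovaSeq instrument, per the labels' protocols. The 18 libraries fall into 6 groups of 3: wildtype mice given PBS, 5xFAD mice given PBS and 5xFAD mice given extracellular vesicles from human breast milk, each in both tissues. Groups and replicate numbers were taken from the sample titles, and all 18 columns of the table matched a sample by name. Nothing in the labels says that the 3 replicates of a group are separate mice, or that the same number in both tissues is the same mouse, so p-values measure only the spread between these samples, which may be technical. In 1 comparison, 5xFAD PBS against wildtype in prefrontal cortex, libraries with the same number deviated together from their group means (correlations of 0.213, 0.509 and 0.169, all over 0.1). This pairing comes from the values, not the labels, so values with the replicate number as a block are given there where they change a call. It holds only in part, since wildtype replicate 3 correlated best with 5xFAD PBS replicate 1, not 3. The pair at 0.509 also shares a trend over gene length (slopes of -0.101 and -0.0796). No other comparison of groups had all its pairs over 0.1. The pairs were judged per comparison only after the counts under the block had been seen.

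The deposited table holds FPKM (fragments scaled by gene length and by library size) for 18683 genes, with gene symbols, Entrez identifiers and, for 17021 genes, Gene Ontology terms. The tools fastp, HISAT2 and HTSeq and the genome build GRCm39 are named per the submitters' processing notes, without version, role or order. The annotation, the gene lengths behind the FPKM, the filter that set the list of genes and the use of strand are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and how reads shared by near-identical genes were counted is open, so values of the H2, Oas, Ifit, Hba and Hbb families are uncertain between members. The reference annotation at hand was GRCm38.p6, another build, so no coordinates are given and it was used only for names: 18557 genes matched by Entrez identifier, 18390 of them protein coding. Genes encoded by the mitochondrial genome were not analysed here.

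The depth was read from the deposited FPKM values. Each library's values were first divided by a constant of that library. Within a gene, the 18 values were whole multiples of a common step for 100% of the 18683 genes, within a relative tolerance of 1e-06. These multiples give the reads behind each value. Gene lengths recovered in the same way were whole within 0.01 for 99.6% of genes. The listed genes held 26437852 to 36901744 reads per library, and 1 read on a gene of median length was worth 0.00843 to 0.0118 FPKM, so sampling of reads limits only genes well under 0.5 FPKM. No replicate pair was a repeated library: the chi-square per gene between replicates ranged from 10.4 to 78.7.

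FPKM is not a count, so tests ran on log2(FPKM + 0.5), and fold changes are on that scale, which understates the change of genes with low values. Within each tissue the 9 libraries were fitted together with a mean per group in limma 3.58.1 (R 4.3.3), with eBayes variance moderation and an intensity trend, after keeping genes with at least 0.5 FPKM in at least 3 of the 9 libraries (13055 genes in prefrontal cortex, 13305 in hippocampus). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Every adjusted p given for a gene is from limma. Differences between tissues were fitted on all 18 libraries (13574 genes). The 46 gene lists (pathways, cell types and brain regions), the comparisons, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 3 tested members were tested with camera, which compares the members with all other genes, at a preset correlation between genes of 0.01, and again with the correlation estimated from the data; fry was an alternative. Gene Ontology terms with 10 to 200 tested genes, as the deposited table lists them, were tested in the same way. Counts adjusted over the list alone correct for the members of that list only. Single values were compared by exact permutation tests, two-sided, for which 3 against 3 libraries cannot give a p below 0.1.

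Named genes followed 1 rule. App, Thy1 and Cd36 were named in every comparison, App and Thy1 because 5xFAD mice carry human APP under a Thy1 promoter, so that reads of the transgene may be counted on these mouse genes. Some genes that the rule selects are not reported here. Per comparison, the 10 largest rises and the 10 largest falls were taken among called genes without overlap between the groups' libraries and with at least 1 FPKM in the higher group, leaving out symbols of unnamed gene models and pseudogenes; where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were taken and said not to have passed. Per list, up to 4 members with the smallest unadjusted p were taken, and for each difference between tissues the 5 with the smallest p per direction. Genes called in opposite directions by genotype and by vesicles would have been named, but vesicles gave no called gene in either tissue, so there could be none. Where a symbol had several entries, the one with the highest mean was used.

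The procedure was tested on simulated data with the real means and spread, drawn independently for each gene. Changed genes were picked only among those with a mean level over 1 FPKM on the log2 scale, so recovery below that was not measured. For 5xFAD PBS against wildtype PBS it recovered 58% (prefrontal cortex, 12955 genes simulated) and 64% (hippocampus, 13186 genes) of 50 genes changed 1.5-fold, 85.3% in both tissues of 75 genes changed 2-fold, and 100% and 98.7% of 75 genes changed 4-fold; 5 of 173 and 14 of 184 calls were false. Alternatives fixed in advance were other pseudocounts (0.1 and 1), other filters, median-of-ratios scaling, quantile normalization, library weights, other sets of libraries in the fit, a replicate block, an unadjusted threshold, the other list tests and leaving out each library. Chosen after seeing the data were voom on the recovered reads, a correction for gene length, a covariate for choroid plexus transcripts, leaving out each library for the lists of the tissue differences, and fits without a library that held transcripts of another tissue.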

Results

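Transcripts were measured in 2 brain regions, prefrontal cortex and hippocampus, from male mice. The mice were C57BL/6J wildtypes or 5xFAD, a strain that carries mutated human APP under a Thy1 promoter and forms amyloid plaques in the brain. Wildtype mice received PBS. 5xFAD mice received PBS or extracellular vesicles (EV), the membrane-bound particles that cells release, here from human breast milk. Doses went into a vein every 3 days, 10 in all, between 5 and 6 months of age, and tissue was taken after behavioural tests. Each of the 6 combinations of tissue and group had 3 libraries. Reads in listed genes ranged from 26437852 (5xFAD EV hippocampus, replicate 3) to 36901744 (5xFAD EV hippocampus, replicate 2). Levels below are mean FPKM ± SD over n = 3 libraries, and fold changes are differences of log2(FPKM + 0.5), with standard errors (SE) where given.

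The comparison of 5xFAD with wildtype mice, both given PBS, shows differences by genotype after the course of injections, without vesicles. In prefrontal cortex, microglial genes rose and genes that neurons switch on with activity fell. Cst7, which encodes the cysteine protease inhibitor cystatin F, rose from 0.351 ± 0.222 to 71.6 ± 6.16 FPKM (log2 fold change 6.43, SE 0.18, adjusted p = 5e-08). Trem2, a microglial lipid receptor, rose from 9.72 ± 2.75 to 54.6 ± 2.44 (2.47, SE 0.17, adjusted p = 6.3e-05), and Gfap, an astrocyte filament protein, from 36.3 ± 10.2 to 139 ± 23.5 (1.94, SE 0.17, adjusted p = 0.00027). Arc, an immediate early gene of synaptic plasticity, fell from 80.7 ± 19.3 to 18.6 ± 14.1 (-2.31, SE 0.43, adjusted p = 0.021, and 0.061 with the replicate number as a block, where it did not pass). Thy1, whose promoter drives the transgenes, rose from 469 ± 31.9 to 1098 ± 51.4 (1.23, SE 0.14, adjusted p = 0.00095). App (100.5 ± 1.67 against 103 ± 4.6) and the fatty acid and scavenger receptor Cd36 (0.732 ± 0.488 against 0.393 ± 0.0528, adjusted p = 0.98) did not pass.

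Of the 32 measured genes of disease-associated microglia, the state described around plaques, 22 rose (25 adjusted over the list alone, median log2 fold change 1.19), and of 14 markers of microglia in all states, 13 rose (14 over the list alone, 1.23). Among the largest rises were the beta-glucan receptor Clec7a (4.02), the chemokines Ccl6 (3.23) and Ccl3 (3.12), the integrin Itgax (2.80), Cd52 (2.44), the lysosomal glycoprotein Cd68 (2.17), lysozyme Lyz2 (2.13) and Cd180 (2.08). Of 15 genes of homeostatic microglia 11 rose (13 over the list alone, 0.75), among them Csf1r (0.85), which microglia need to survive, Olfml3 (1.25) and Tgfbr1 (0.71). Complement followed with 9 of 12 higher (9 over the list alone, 1.12), with C1qa at 143 ± 2.33 against 51.9 ± 9.8 and C4b at 9.91 ± 1.94 against 2.99 ± 0.396. MHC class I presentation had 6 of 10 higher (9 over the list alone, 0.56), including the peptide transporter Tap1 (1.03) and B2m (0.83). Scavenger and phagocytic receptors had 8 of 17 higher (8 over the list alone, 0.37), including Cd14 (1.49). Reactive astrocyte genes had 3 of 13 higher (4 over the list alone, and 1 lower, 0.28), including Serpina3n (1.08). With the exception of homeostatic microglia (adjusted p = 0.062), these lists also passed with an estimated correlation, at adjusted p = 0.026 (disease-associated microglia, all microglia, complement and MHC class I), 0.030 (scavenger receptors) and 0.045 (reactive astrocytes).

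Lysosomal genes rose with 11 of 25 members (12 over the list alone, median 0.23, adjusted p = 0.11 with an estimated correlation), among them Grn (1.08), which encodes progranulin, Naglu (0.91) and Hexa (0.85), and the protease Ctsd rose from 223 ± 15.1 to 607 ± 36.8. MHC class II presentation had 2 of 6 members higher (6 over the list alone, median 1.01, adjusted p = 0.090 with an estimated correlation), led by Cd74 (1.60). The type I interferon list rose with 3 of 19 members (16 over the list alone, 0.80, adjusted p = 0.17 with an estimated correlation): Oas1a (1.09), Ifit2 (0.52) and Trim30a (0.84). With the replicate block the list passed but these 3 genes did not (adjusted p = 0.061, 0.066 and 0.081). Cytokines and NF-kB had 3 of 17 higher (5 over the list alone, and 1 lower, 0.19, adjusted p = 0.20 with an estimated correlation), including the receptor Tlr2 (1.25), but this list did not pass without wildtype replicate 3 or without 5xFAD PBS replicate 1. Cholesterol synthesis rose with 4 of 23 members (13 over the list alone, 0.31, adjusted p = 0.098 with an estimated correlation), among them Fdps, from 40.4 ± 2.51 to 58.2 ± 7.39, and Stard4 (0.58).

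Immediate early genes fell as a list, with 9 of 20 members lower (15 over the list alone, median -0.97, adjusted p = 0.062 with an estimated correlation). Besides Arc these included the transcription factors Egr2 (-1.83), Nr4a1 (-1.87), Egr1 (-1.54), Fosb (-0.99) and Fosl2 (-1.05) and the phosphatases Dusp1 (-1.32) and Dusp6 (-0.93). With the replicate block the list and Egr2 (adjusted p = 0.024) passed, but Nr4a1 (0.065), Egr1 (0.064), Fosb (0.061), Fosl2 (0.065), Dusp1 (0.058) and Dusp6 (0.073) did not. The list passed in every fit that left out 1 of the 6 libraries, but among these genes Egr2 alone did so, and Klf10 (-0.94), called with all libraries, was called in none of those fits. The unfolded protein and heat shock list fell as a whole (median -0.18, 0 of 17 members called, 3 lower over the list alone, adjusted p = 0.20 with an estimated correlation), with the chaperone Hspa5 at 97.1 ± 10.3 against 142 ± 34.2. Nuclear genes of oxidative phosphorylation had 33 of 35 values below 0 (median -0.11, 0 called, also over the list alone, adjusted p = 0.76 with an estimated correlation), a call that was lost without wildtype replicate 2. Ependymal markers were higher as a list (0.38, 0 of 8 called, also over the list alone, adjusted p = 0.76 with an estimated correlation), and this call was lost without wildtype replicate 1 and without 5xFAD PBS replicate 2. Lists for neurons, presynaptic and postsynaptic proteins, oligodendrocytes, endothelial and mural cells, choroid plexus, autophagy, amyloid precursor processing and glycolysis were among those that did not pass. Nor did ribosomal proteins (0.09, adjusted p = 0.18), which passed with the replicate block (adjusted p = 0.015).

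In all, limma called 256 of 13055 genes in prefrontal cortex, 238 higher and 18 lower, of which 100 changed over 2-fold. Voom on the recovered reads called 250. None of the 256 had overlapping groups, against 14.7% of all tested genes without overlap and 10% by chance. With 3 libraries per group, a gene that passes the threshold is nearly bound to be without overlap. This therefore adds no support to the calls, here or in the comparisons below. The count fell to 143 without wildtype replicate 1, 157 without wildtype replicate 3, and 147, 144 and 142 without 5xFAD PBS replicates 1, 2 and 3. 113 of the 256 genes were called in every such fit and none changed sign.

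**Figure D1:**
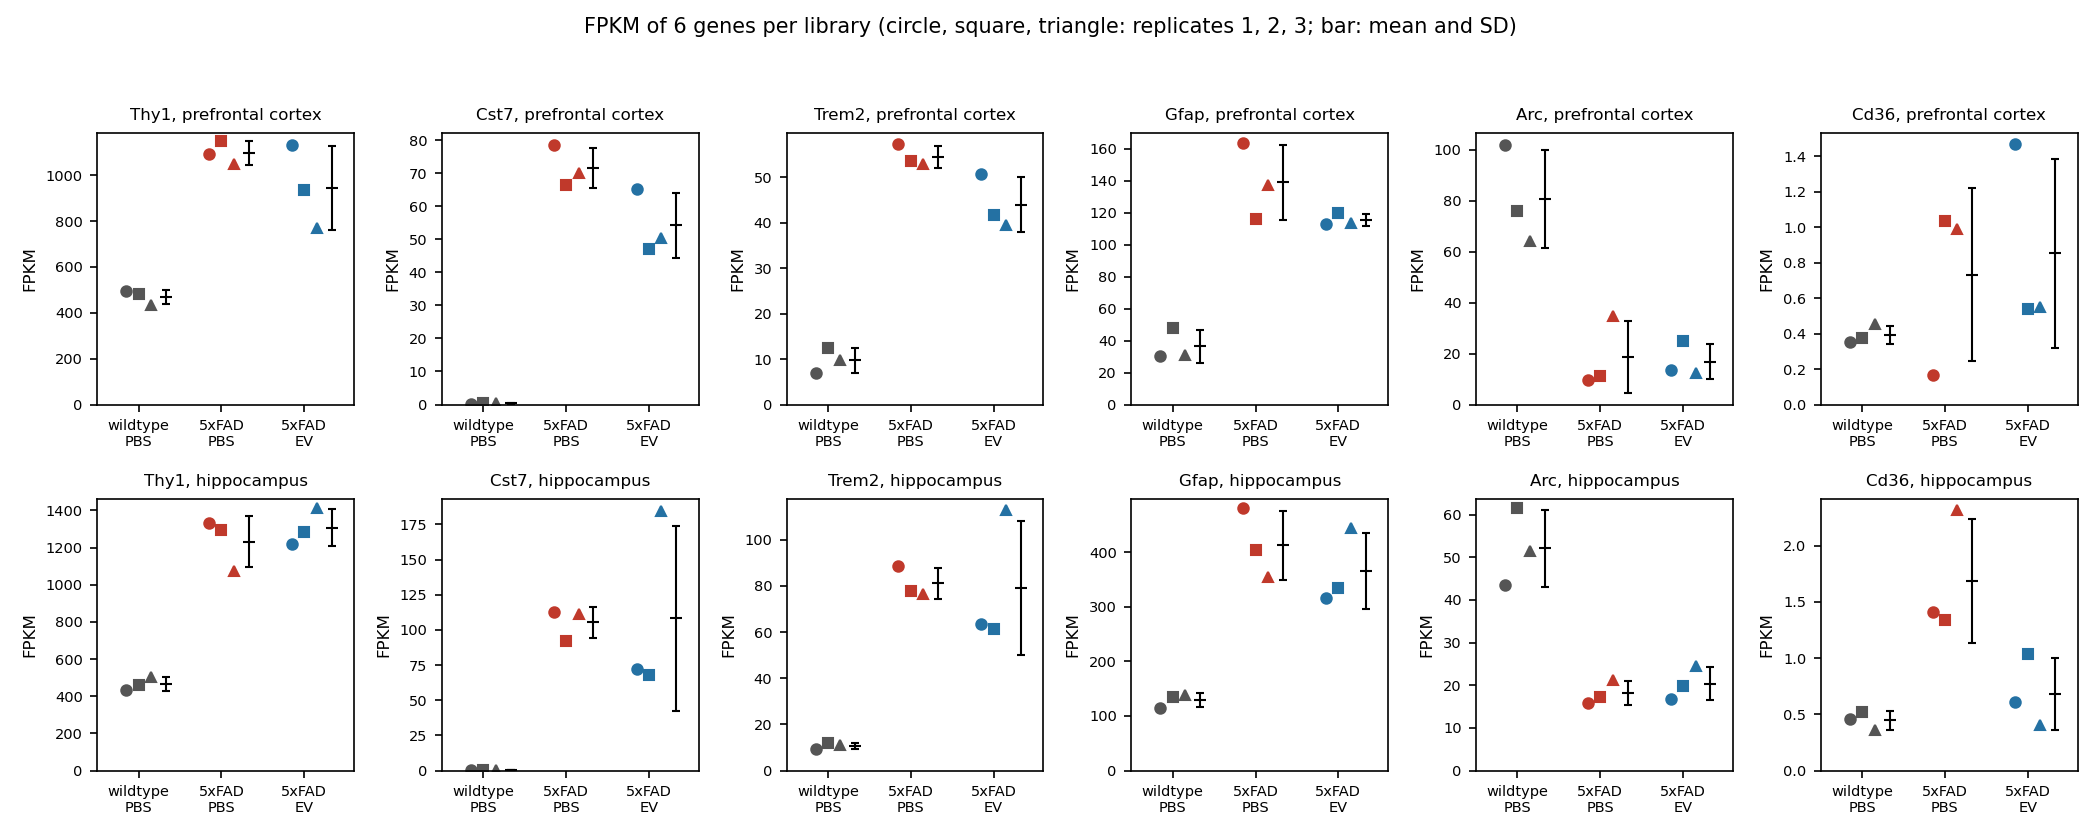
FPKM of Thy1, Cst7, Trem2, Gfap, Arc and Cd36 in each library of the prefrontal cortex (upper panels) and hippocampus (lower panels), by group, with replicates 1, 2 and 3 as circle, square and triangle and the mean and SD of 3 libraries beside them. Thy1, Cst7, Trem2 and Gfap lie higher and Arc lower in all 5xFAD libraries than in wildtype, and Cd36 in hippocampus has means of 0.446, 1.69 and 0.683 in wildtype PBS, 5xFAD PBS and 5xFAD EV.

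In hippocampus, the same comparison again gave higher microglial and lower immediate early transcripts, together with higher antigen presentation, interferon and choroid plexus genes. Cst7 rose from 0.281 ± 0.124 to 105 ± 11.2 FPKM (7.09, SE 0.32, adjusted p = 1.8e-05). Trem2 rose from 10.7 ± 1.34 to 81.1 ± 6.58 (2.86, SE 0.21, adjusted p = 0.00019) and Cd74, the invariant chain of MHC class II, from 5.47 ± 3.19 to 68.6 ± 34 (3.54, SE 0.54, adjusted p = 0.0051). Arc fell from 52.1 ± 9.01 to 18.1 ± 2.79 (-1.50, SE 0.17, adjusted p = 0.0011). Cd36 rose from 0.446 ± 0.0819 to 1.69 ± 0.55 (1.18, SE 0.22, adjusted p = 0.015), a call that was lost without wildtype replicate 3 (adjusted p = 0.062) and in 1 further fit that left out a library. Thy1 rose from 465 ± 37.2 to 1232 ± 138 (1.40, adjusted p = 0.00062), while App (91.1 ± 2.86 against 102 ± 1.26, adjusted p = 0.27) did not pass.

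Disease-associated microglia had 26 of 32 genes higher (30 over the list alone, median 1.82, adjusted p = 0.088 with an estimated correlation). All 14 microglial markers rose (14 over the list alone, 1.73, adjusted p = 0.096 with an estimated correlation). Homeostatic microglia had 11 of 15 higher (14 over the list alone, 0.99, adjusted p = 0.14 with an estimated correlation). Clec7a (4.61), Ccl3 (3.51), the pore-forming protein Mpeg1 (2.63) and the chemokine receptor Cx3cr1 (1.30) were among them. Complement had 8 of 13 higher (11 over the list alone, 1.23), MHC class I 9 of 10 (10 over the list alone, 1.37) and scavenger receptors 9 of 17 (11 over the list alone, 0.87), each at adjusted p = 0.088 with an estimated correlation. C1qa stood at 242 ± 17.5 against 55.4 ± 6.26, B2m at 616 ± 16.9 against 201 ± 13.7 and the Fc receptor Fcgr2b rose by 2.32. MHC class II had 5 of 6 higher (6 over the list alone, 2.64, adjusted p = 0.15 with an estimated correlation). The interferon list had 11 of 19 higher (18 over the list alone, 1.39, adjusted p = 0.19 with an estimated correlation), including Bst2, which tethers viruses at the cell surface (2.21), Ifit3 (1.77), Trim30a (1.65) and Ifitm3, from 32 ± 2.23 to 88.4 ± 32.5. Lysosomal genes had 15 of 25 higher (17 over the list alone, 0.58, adjusted p = 0.16 with an estimated correlation), with Ctsd, of the amyloid degradation list, at 915 ± 47.4 against 238 ± 26.1. That list itself did not pass (median 0.27, 2 of 9 called). Reactive astrocyte genes had 4 of 14 higher (10 over the list alone, 0.76, adjusted p = 0.21 with an estimated correlation), with Gfap at 413 ± 63.7 against 130 ± 12.9. Cytokines and NF-kB had 7 of 19 higher (10 over the list alone, and 1 lower, 0.43, adjusted p = 0.14 with an estimated correlation), including Cxcl16 (1.58).

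Lipid and stress genes moved as well. Cholesterol synthesis had 9 of 23 higher (11 over the list alone, 0.34, adjusted p = 0.088 with an estimated correlation), including squalene epoxidase Sqle, from 22.3 ± 0.865 to 32.1 ± 1.26, and Nsdhl (0.65). Fatty acid uptake and oxidation had 3 of 30 higher (8 over the list alone, 0.26) and the antioxidant response 3 of 18 (3 over the list alone, 0.20), each at adjusted p = 0.33 with an estimated correlation. They included the lipid droplet protein Plin2 (0.70), Fabp7 (0.65), Cpt2 (0.84), the transcription factor Nfe2l2 (0.87) and its target Nqo1 (0.98). Neutrophil and monocyte markers had 2 of 4 higher (4 over the list alone, 1.09, adjusted p = 0.15 with an estimated correlation), including S100a8 (1.55). Ribosomal proteins were higher as a list with 0 of 38 called, also over the list alone (0.20, adjusted p = 0.63 with an estimated correlation), a call lost without wildtype replicate 1 and without 5xFAD PBS replicate 2.

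Immediate early genes had 8 of 20 lower (12 over the list alone, -0.60, adjusted p = 0.088 with an estimated correlation), among them Nr4a1 (-1.36), Fos (-1.33), Egr1 (-1.04) and Junb (-0.75). Glutamatergic neuron markers fell as a list with 1 of 10 called, also over the list alone (-0.21, adjusted p = 0.088 with an estimated correlation). GABAergic markers fell as a list with 0 of 12 called and 2 lower over the list alone (-0.29, adjusted p = 0.19 with an estimated correlation). So did presynaptic genes with 0 of 23 (-0.19, adjusted p = 0.33 with an estimated correlation) and postsynaptic genes with 0 of 24 (-0.21, adjusted p = 0.40 with an estimated correlation), both also 0 over the list alone. Mean slopes over gene length were 0.0230 (SD 0.0790) in wildtype and -0.0517 (SD 0.103) in 5xFAD PBS libraries, with overlap between them. With that trend removed postsynaptic genes still passed (-0.16, camera adjusted p = 0.0011, and 0.23 with an estimated correlation). The kinase Itpka fell from 144 ± 19.7 to 99.95 ± 9.39, and the NMDA receptor subunit Grin1 stood at 78.6 ± 7.8 against 98.6 ± 3.46 (adjusted p = 0.13). Oligodendrocyte genes had 1 of 14 lower, also over the list alone (-0.15, adjusted p = 0.40 with an estimated correlation), the myelin gene Mobp (-0.42). The unfolded protein list was lower (-0.09, 1 of 17 higher, 1 higher and 4 lower over the list alone, adjusted p = 0.45 with an estimated correlation), a call lost without wildtype replicate 1 and without 5xFAD PBS replicate 1 or 3. Among single genes the falls included Saa3 (-2.50), the transcription factor Elk1 (-1.31), Cort (-1.05), Dusp5 (-0.98) and Gpr3 (-0.83). Elk1 and Gpr3 were called in no fit that left out 1 of the 6 libraries, and Saa3 in 1. Elk1 stood at 23.9 FPKM in EV replicate 3. In prefrontal cortex it stood at 20.3 in 5xFAD PBS replicate 3, against 17.7 to 19.3 in wildtype. Its fall was thus not shared by all 5xFAD libraries, with or without EV, and what it follows is open.

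Transcripts of the choroid plexus, the tissue that secretes cerebrospinal fluid, were far more abundant in 5xFAD hippocampus. Its 13 markers were all higher, 8 of them called (13 over the list alone, median 3.64, adjusted p = 0.24 with an estimated correlation), and they included some of the largest rises: Ttr, a thyroid hormone carrier, at 4638 ± 3505 against 88.3 ± 65.3 (5.76, SE 1.12, adjusted p = 0.018), Kcne2 (4.27), Clic6 (4.12), Aqp1 (3.74), F5 (3.69) and Kcnj13 (3.69), while Prr32 (3.97), Steap1 (3.75) and Defb11 (3.69) also rose. Of these, Kcne2, Aqp1, F5 and Defb11 were called in no fit that left out 1 of the 6 libraries. Meningeal fibroblast markers rose beside them, with 1 of 11 called (5 over the list alone, 0.81, adjusted p = 0.37 with an estimated correlation). With the mean of the choroid plexus markers as a covariate, 278 genes were called. Disease-associated microglia then had a median of 2.53 with 23 members called, higher than without the covariate. The presynaptic (0.01), glutamatergic (-0.14), GABAergic (-0.06), oligodendrocyte (-0.08), meningeal (0.40), unfolded protein (-0.13) and choroid plexus lists (-0.03) no longer passed. That covariate largely follows genotype. Less the wildtype mean it was -0.301 to 0.282 in wildtype libraries and 2.69 to 4.38 in all 5xFAD libraries but EV replicate 3 (0.232). The adjustment therefore rests largely on that library, and these fits do not separate choroid plexus content from genotype. Under that covariate 6 other lists passed: astrocyte (0.38, adjusted p = 0.19 with an estimated correlation), neocortical neuron (0.39, 0.48 likewise) and endothelial markers (0.25, 0.61) in the higher direction, and ependymal (-1.78, 0.21), layer 5 neuron (-0.20, 0.32) and hippocampal neuron markers (-0.20, 0.53) in the lower. Under this covariate 5 lists passed with an estimated correlation (the covariate was chosen after results were seen): MHC class I, cytokines and cholesterol synthesis (each at adjusted p = 0.035), and disease-associated and all microglia (both 0.041).

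In hippocampus limma called 611 of 13305 genes, 557 higher and 54 lower, of which 312 changed over 2-fold. Voom called 545. All 611 were without overlap between groups, against 25.5% of tested genes and 10% by chance. After quantile normalization the split was 375 higher and 94 lower, and with the trend over gene length removed 700 and 248. The count was 370, 320 and 405 without wildtype replicates 1, 2 and 3, and 397 and 373 without 5xFAD PBS replicates 1 and 2. 288 of the 611 genes were called in every such fit.

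The genotype effects of the tissues shared many genes. Among 12851 genes tested in both, 210 were higher in both (238 in prefrontal cortex and 521 in hippocampus, 9.65 expected of independent lists) and 7 were lower in both (18 and 54, 0.0756 expected). The test of the difference between tissues called 0 of 13574 genes in limma (787 at an unadjusted p under 0.05, smallest adjusted p = 0.53). The smallest p-values were those of Slc37a2 (1.03 higher effect in hippocampus), Tent5c (0.80), Sowahc (1.001), the lysosomal membrane protein Lamp2 (0.56) and Ehd4 (0.63), and of Cldn22 (-0.79), Kcnj11 (-0.56), Snx22 (-0.56), Psrc1 (-0.87) and Osbp2 (-0.43), none of which passed. By list, 24 of 45 genotype effects differed between tissues with the preset correlation, 19 of them higher in hippocampus, and 0 with an estimated correlation (lowest adjusted p = 0.17). The difference was 3.52 for choroid plexus (adjusted p = 0.30 with an estimated correlation), 0.77 for MHC class I (0.17 by the same measure) and 0.43 for disease-associated microglia (0.33 by the same measure).

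The comparison of EV with PBS in 5xFAD mice asks what the vesicles changed. In prefrontal cortex no single gene passed, but interferon-responsive and microglial genes were lower and vascular genes higher as lists. The means of the microglial and endothelial lists overlapped between EV and PBS libraries. The type I interferon list had 17 of 19 members below 0 (median -0.53, camera adjusted p = 3.03e-11, adjusted p = 0.54 with an estimated correlation). Its mean differed by -0.49 (exact permutation p = 0.1), while wildtype libraries alone had an SD of 0.496. Members included the transcription factor Irf7 at 2.71 ± 0.553 with EV against 5.67 ± 0.806 with PBS. Oasl2 was at 3.17 ± 0.707 against 6.62 ± 0.549. Endothelial markers were higher (median 0.31, 8 of 13 adjusted over the list alone, adjusted p = 0.54 with an estimated correlation), with the adhesion molecule Pecam1 at 8.36 ± 0.756 against 6.63 ± 0.0794. Mural cell markers were higher too (0.35, 5 of 10 over the list alone, adjusted p = 0.54 with an estimated correlation), with the contractile protein Myh11 at 2.15 ± 0.633 against 1.22 ± 0.265. Red blood cell markers were higher in the same comparison (2.09), so more vessel or blood in the EV blocks is not excluded. Thy1 (946 ± 183 against 1098 ± 51.4), App (97.9 ± 3.09) and Cd36 (0.853 ± 0.534 against 0.732 ± 0.488, adjusted p = 0.91) did not pass.

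All 14 microglial markers were below 0 (median -0.23), as were 24 of 32 genes of disease-associated microglia (-0.15), with Cst7 at 54.3 ± 9.78 against 71.6 ± 6.16 and Cd52 at 18.7 ± 2.23 against 28.6 ± 2.38. Less the wildtype mean, the all-microglia mean was 1.25, 0.966 and 0.858 in EV replicates 1, 2 and 3 against 1.22 to 1.29 with PBS. EV replicate 1 thus lay at the PBS level. For homeostatic microglia it lay above the PBS libraries (0.802 against 0.699 to 0.771). Homeostatic microglia (-0.17), complement (-0.16), MHC class I (-0.07), lysosome (-0.05), autophagy (-0.05), cholesterol synthesis (-0.10), glycolysis (-0.13), neuron (-0.07) and glutamatergic neuron markers (-0.18), immediate early genes (-0.20), ribosomal proteins (-0.11), oxidative phosphorylation (-0.05) and striatal neuron markers (-0.85) also passed in the lower direction. Olfactory bulb and piriform markers (0.97), red blood cell markers (2.09, 2 of 5 over the list alone), meningeal fibroblast (0.38) and astrocyte markers (0.13) passed in the higher direction. With an estimated correlation each of these 22 lists, 6 higher and 16 lower, had an adjusted p of 0.54 except ribosomal proteins (0.65) and oxidative phosphorylation (0.78), and fry called 0. Over the list alone no member passed in any of them but the endothelial, mural and red blood cell lists. Of the single genes, Plac9a (13.2 ± 3.25 against 6.77 ± 1.05), Tmem254a, Map3k1, the organic anion transporter Slco1a4 and Reck had the smallest p-values among higher ones. Among lower ones these were Isoc2b (2.45 ± 0.248 against 4.14 ± 0.148), Zbp1, a sensor of nucleic acids (0.512 ± 0.0474 against 1.11 ± 0.093), Lgals9, Pdcd1 and Ifi47, all 10 genes at adjusted p = 0.82.

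Several lists moved with single libraries. Replicate 3 of the EV group held cerebellar transcripts, such as the granule cell receptor Gabra6 at 89.8 FPKM against at most 0.133 in the other prefrontal libraries, and choroid plexus transcripts, with Ttr at 836 against at most 11.6. Without it the interferon (-0.52) and microglial lists (-0.15) still passed, and the immediate early (-0.07, adjusted p = 0.20), ribosomal (-0.06, 0.068), glutamatergic (-0.02, 0.97), cholesterol synthesis (-0.04, 0.26) and meningeal lists (0.20, 0.082) did not, nor did homeostatic microglia, complement and astrocyte markers. Without this library 14 lists passed. The striatal list depended on EV replicate 1, without which it did not pass, and its dopamine receptor Drd2 was at 5.76 ± 7.88 against 9.3 ± 2.38. Haemoglobin Hba-a2, a measure of blood left in the tissue, was at 4.09 ± 2.21 with EV against 0.548 ± 0.46. Other calls ended without EV 1 or PBS 1 (MHC class I, astrocytes), EV 1 or PBS 2 (oxidative phosphorylation), EV 2 (lysosome, complement), PBS 1 (glutamatergic and meningeal markers), PBS 2 (ribosomal proteins), PBS 3 (immediate early genes) and any library but PBS 3 (autophagy). After quantile normalization oxidative phosphorylation turned to 0.02 (adjusted p = 0.33), and the ribosomal (-0.03, adjusted p = 0.28), glutamatergic (-0.10, 0.12) and lysosome lists (-0.04, 0.073) did not pass. With the trend over gene length removed oxidative phosphorylation (adjusted p = 0.94) and MHC class I did not pass. limma called 0 of 13055 genes, with 616 at an unadjusted p under 0.05 (653 expected with no effect), and voom 0 with 634. The smallest adjusted p was 0.82, and 1 gene was called without 5xFAD PBS replicate 1.

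In hippocampus, EV again left no single gene past the threshold, with lower interferon, antigen presentation and meningeal lists and higher synaptic lists. Cd36 was at 0.683 ± 0.32 with EV against 1.69 ± 0.55 with PBS (-0.89, SE 0.22, adjusted p = 0.87) with 0.612, 1.03 and 0.404 in the EV libraries and 1.41, 1.34 and 2.32 in the PBS libraries. The interferon list had 18 of 19 members below 0 (median -0.86, 11 lower over the list alone, camera adjusted p = 2.09e-12, adjusted p = 0.49 with an estimated correlation), with Ifitm3 at 38.9 ± 5.96 against 88.4 ± 32.5, Bst2 at 18.4 ± 2.29 against 37.4 ± 13.5 and Isg15, a ubiquitin-like modifier, at 6.75 ± 3.03 against 15.9 ± 5.53. The mean of the interferon list differed by -0.75 between EV and PBS (exact permutation p = 0.2), with overlap between their libraries. All 24 postsynaptic genes were above 0 (0.17), with the NMDA receptor subunit Grin2a at 14.5 ± 1.59 against 11.1 ± 2.2. Members share the same libraries, so their number does not count replicates. Less the wildtype mean, the list mean overlapped between groups, at 0.0882, 0.121 and -0.216 with EV and 0.0162, -0.440 and -0.163 with PBS. Values also trended with gene length, at mean slopes of 0.0287 (SD 0.0778) with EV and -0.0517 (SD 0.103) with PBS, with overlap between their libraries. With that trend removed the postsynaptic median was 0.07 (camera adjusted p = 0.00034). With an estimated correlation the list did not pass, at adjusted p = 0.49, or 0.37 with the trend removed. Thy1 (0.09) and App (0.10) did not pass.

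MHC class I had 10 of 10 members below 0 (-0.37) and MHC class II 5 of 6 (-0.58), with H2-Aa at 13.6 ± 4.68 against 23.8 ± 9.47. Fatty acid uptake and oxidation (-0.19), with the mitochondrial carnitine palmitoyltransferase Cpt2 at 3.19 ± 0.664 against 5.39 ± 1.09, the antioxidant response (-0.14), reactive astrocytes (-0.29), neutrophils and monocytes (-0.49, 1 of 4 lower over the list alone), ribosomal proteins (-0.23, 38 of 38 below 0), oxidative phosphorylation (-0.19) and thalamic neuron markers (-0.44) passed in the lower direction. Less the wildtype mean, the ribosomal mean overlapped between groups (-0.112, -0.225 and 0.256 with EV, 0.00028, 0.489 and 0.123 with PBS). The MHC class I mean overlapped too, with EV replicate 3 at 1.31 against 1.18 to 1.56 with PBS. Presynaptic (0.11) and glutamatergic markers (0.14) and red blood cell markers (1.67, 1 of 4 over the list alone, Hba-a2 3.22 ± 1.7 against 0.714 ± 0.375) passed in the higher direction. Meningeal fibroblast markers had 11 of 11 below 0 (-0.94, 4 lower over the list alone), with Ogn at 5.86 ± 0.586 against 13.5 ± 5.55, and choroid plexus markers 13 of 13 (-1.08). With an estimated correlation these 16 lists, 4 higher and 12 lower, had adjusted p = 0.49 or 0.68, fry called 0, and over the list alone no other member passed. Disease-associated microglia (-0.11, adjusted p = 0.23) and all microglia (-0.11, adjusted p = 0.32) did not pass. Among single genes, Klf10 (0.46), Kcnh3 (0.37), Rtn4rl2 (0.33), Syna (0.35) and Mchr1 (0.29) had the smallest p-values among higher ones and S100a8 (0.506 ± 0.0836 against 1.41 ± 0.339), Tnfsf10 (-0.66), Ms4a6b (-0.73), Cfp (-0.63) and Ly6a (25.4 ± 5.7 against 43.2 ± 6.26) among lower ones, each at adjusted p = 0.87.

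Ttr stood at 5532, 2207 and 178 FPKM in EV replicates 1, 2 and 3 and at 2532, 8684 and 2697 in the PBS libraries, and the choroid plexus call was lost without EV replicate 3. With the choroid plexus covariate, chosen after results were seen, the interferon list kept a median of -1.02, and the presynaptic (0.06, adjusted p = 0.091) and choroid plexus lists (0.01, 0.78) no longer passed. This adjustment rests largely on EV replicate 3, which also had the highest mean of the microglial markers (2.11 less the wildtype mean). Another 10 lists passed under the covariate. Disease-associated microglia (-0.28), all microglia (-0.36), homeostatic microglia (-0.17), complement (-0.24), cytokines (-0.22), scavenger receptors (-0.22), lysosome (-0.12), astrocyte (-0.15) and endothelial markers (-0.21) were lower and ependymal markers (0.35) higher. With an estimated correlation 0 lists passed under the covariate (lowest adjusted p = 0.21, and 0.46 for disease-associated and all microglia). With the trend over gene length removed oxidative phosphorylation (-0.01, adjusted p = 0.38) and neutrophils and monocytes (-0.27, 0.17) did not pass. Other calls that leaving out a library ended were MHC class II (5xFAD PBS 1 or 3, EV 1), reactive astrocytes and neutrophils (PBS 1, EV 1), oxidative phosphorylation (PBS 2), antioxidant response (EV 1) and thalamic neurons (PBS 3). limma called 0 of 13305 genes, with 519 at an unadjusted p under 0.05 (75 higher, 444 lower, 665 expected with no effect), and voom 0 with 488. 1 gene was called without 5xFAD PBS replicate 3.

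The EV effects were compared between tissues in the same way. limma called 0 of 13574 genes (680 at an unadjusted p under 0.05, smallest adjusted p = 0.99), the smallest p-values being those of Ctsk (-0.98), Hbp1 (-0.68), Ms4a6b (-0.92), Ston1 (-0.80) and the folate receptor Folr2 (-1.14), with the lower EV effect in hippocampus, and of Cldn22 (0.61), Otulinl (0.43), Ap5b1 (0.61), Lypd1 (0.59) and Baiap2 (0.31). Of 45 lists, 20 differed, 10 each way, and 0 with an estimated correlation (lowest adjusted p = 0.38). Glutamatergic neuron markers differed by 0.31 and meningeal fibroblast markers by -1.29 (both at adjusted p = 0.38 with an estimated correlation), and choroid plexus by -1.93 (0.48 by the same measure). The choroid plexus value was -1.09 without EV prefrontal replicate 3 and -0.90 without EV hippocampus replicate 3, and the glutamatergic value 0.15 without EV prefrontal replicate 3, all still called at the preset correlation.

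**Figure D2:**
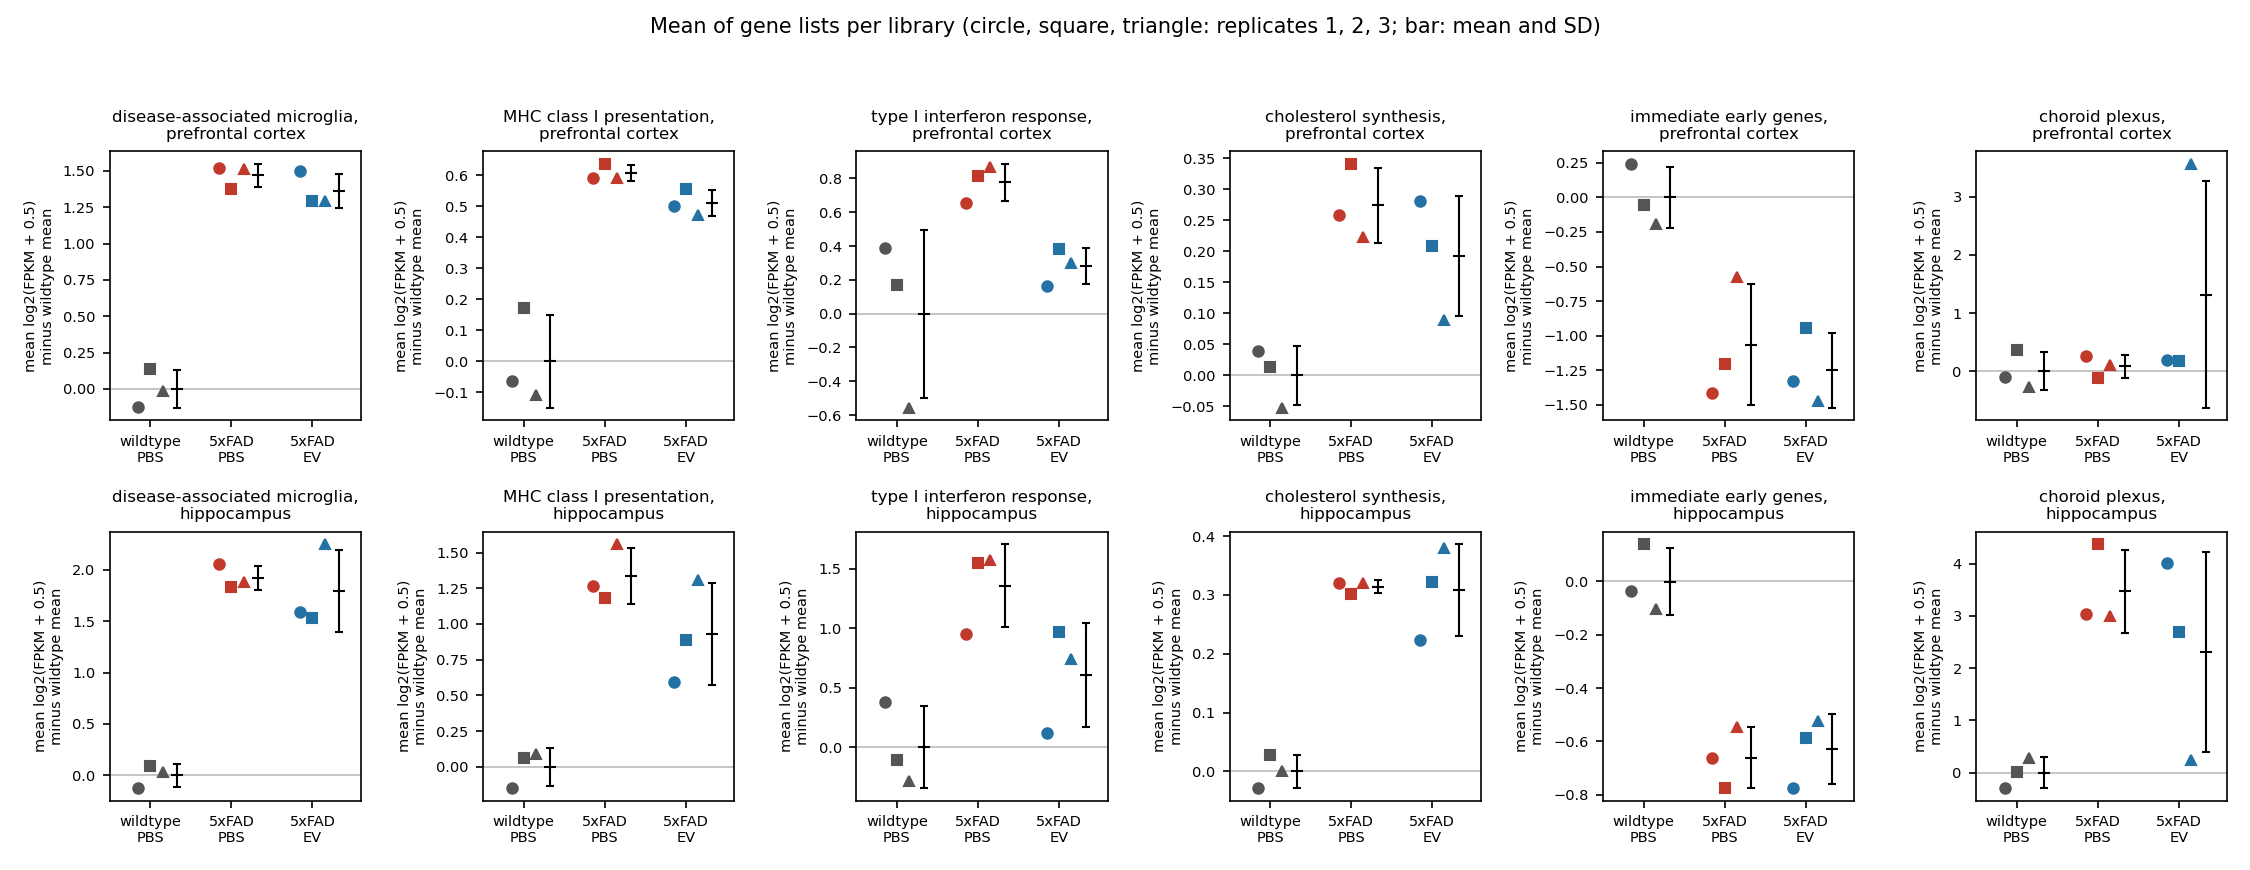
Mean log2(FPKM + 0.5) over the members of 6 gene lists in each library, less the wildtype mean, for prefrontal cortex (upper panels) and hippocampus (lower panels), with the mean and SD of 3 libraries per group. The interferon list lies lower in EV than in PBS libraries of prefrontal cortex, by 0.49 on average, and choroid plexus is high in 1 EV library of prefrontal cortex and in all 5xFAD hippocampus libraries but EV replicate 3.

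Against wildtype, 5xFAD mice given EV showed higher microglial and lower immediate early genes in both tissues. In prefrontal cortex Cst7 rose to 54.3 ± 9.78 (6.03, SE 0.18, adjusted p = 8.1e-08), Trem2 to 44 ± 6 (2.15, SE 0.17, adjusted p = 0.00024) and Thy1 to 946 ± 183 (0.99, adjusted p = 0.0047), and Arc fell to 16.8 ± 6.94 (-2.27, SE 0.43, adjusted p = 0.028). Cd36 (0.53, adjusted p = 0.45) and App (-0.07) did not pass. Clec7a (3.83), Ccl3 (3.28), Ccl6 (3.00), Itgax (2.61), Cd68 (1.93), Lyz2 (1.92), Cd180 (1.86) and Cd52 (1.84) made up the other largest rises, and Egr2 (-2.03), Nr4a1 (-1.99), Egr1 (-1.93), Egr4 (-1.43), Dusp1 (-1.25), Fosb (-1.20), Nr4a3 (-1.16), Fosl2 (-1.08) and Dusp6 (-0.95) the other largest falls. Of these falls Egr2 alone was called in every fit that left out a library, and Dusp1 in none.

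By list in prefrontal cortex, 21 of 32 genes of disease-associated microglia (27 over the list alone), 13 of 14 of all microglia (14 over the list alone), 8 of 12 of complement (9), 3 of 10 of MHC class I (8), 7 of 17 of scavenger receptors (9) and 2 of 13 of reactive astrocytes (7, and 1 lower) rose, each list at adjusted p = 0.073 with an estimated correlation. Homeostatic microglia (6 of 15, 12 over the list alone, adjusted p = 0.21 with an estimated correlation), MHC class II (1 of 6, 6, 0.21 likewise), lysosome (9 of 25, 12, and 1 lower, 0.27), cytokines (3 of 17, 4, 0.22), amyloid degradation (1 of 9, 3, 0.34), cholesterol synthesis (2 of 23, 5, 0.34) and endothelial markers (2 of 13, 9, 0.34) also passed as higher. The interferon list passed with a median of 0.27 and 0 of 19 called (1 over the list alone, adjusted p = 0.64 with an estimated correlation), and not without wildtype replicate 3 or EV replicate 2. Immediate early genes had 10 of 20 lower (19 over the list alone, -1.17, adjusted p = 0.074 with an estimated correlation). Some lists lost their call without single libraries: cytokines (wildtype 3), cholesterol synthesis (EV 1), glutamatergic neurons (EV 3), neurons (wildtype 1), neocortical (wildtype 3 or EV 3) and striatal neurons (wildtype 3 or EV 1). So did meningeal and olfactory markers (wildtype 1 or 3, EV 2 or 3), neutrophils and monocytes (wildtype 2, EV 1 or 3) and autophagy (wildtype 1, EV 2 or 3). With an estimated correlation these had adjusted p from 0.21 (autophagy) to 0.58 (meningeal, striatal and olfactory). Mural cell markers (median 0.36, 5 of 10 over the list alone, adjusted p = 0.22 with an estimated correlation) were higher, and the unfolded protein list (-0.18, 0.22 likewise), oxidative phosphorylation (-0.16, 0.41 likewise) and glycolysis (-0.11, 0.39 likewise) lower. In all 198 of 13055 genes were called, 183 higher and 15 lower (voom 228), all without overlap against 19.3% of tested genes and 10% by chance. The count was 89 and 129 without wildtype replicates 1 and 3 and 105 without EV replicate 1.

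In hippocampus Cst7 (6.97, SE 0.32, adjusted p = 2.1e-05), Clec7a (4.42), Ccl3 (3.61), Ccl6 (3.31), Itgax (3.18), Cd74 (2.92), Trem2 (2.78), Cd180 (2.65), Cd68 (2.63) and Cd52 (4.93 ± 1.77 to 33.4 ± 15.3) rose most. The largest falls were those of Fos (-1.54), Arc (-1.34), Nr4a1 (-1.22), Dusp1 (-1.07), Cort (-1.01), Egr1 (-0.98), Fosb (-0.86), Fv1 (-0.77), Egr4 (-0.75) and the neurosecretory protein gene Vgf (-0.68). Thy1 rose by 1.49. Cd36 (0.29, adjusted p = 0.68) and App (-0.06) did not pass. Disease-associated microglia had 23 of 32 higher (27 over the list alone), all microglia 14 of 14 (14), complement 7 of 13 (9), scavenger receptors 7 of 17 (8) and cholesterol synthesis 6 of 23 (15), and immediate early genes 8 of 20 lower (10), each at adjusted p = 0.072 with an estimated correlation. MHC class I had 5 of 10 higher (9 over the list alone, adjusted p = 0.079 with an estimated correlation), MHC class II 4 of 6 (6, 0.14 likewise), lysosome 12 of 25 (15, 0.14) and the interferon list 2 of 19 (2, median 0.54, 0.37). Choroid plexus markers were higher as a list with 0 of 13 called (12 over the list alone, median 2.33, adjusted p = 0.30 with an estimated correlation), and GABAergic neuron (-0.29, 0.18 likewise) and oligodendrocyte markers (-0.22, 0.29 likewise) were lower. Homeostatic microglia (11 of 15 higher, adjusted p = 0.081 with an estimated correlation), cytokines (5 of 19, 0.081 likewise), reactive astrocytes (2 of 14, 0.29) and neutrophil and monocyte markers (0 of 4, 3 over the list alone, 0.21) were higher as lists. Lower were the unfolded protein list (-0.23, 0.29 likewise), oxidative phosphorylation (-0.14, 0.73), glycolysis (-0.09, 0.63) and autophagy (-0.07, 0.36). These last lists lost their calls without wildtype 1 (unfolded protein), wildtype 3 (oxidative phosphorylation), wildtype 3 or EV 1 (glycolysis) and wildtype 3, EV 1 or EV 2 (autophagy). With the choroid plexus covariate oxidative phosphorylation (-0.09, adjusted p = 0.078), glycolysis (-0.08, 0.34), autophagy (-0.06, 0.40) and choroid plexus markers (-0.14, 0.64) did not pass. Astrocyte (0.23, adjusted p = 0.23 with an estimated correlation), ependymal (-1.32, 0.23 likewise), layer 5 neuron (-0.16, 0.45) and meningeal markers (-0.43, 0.71) passed under it. There 7 lists passed with an estimated correlation: cholesterol synthesis (adjusted p = 0.023), MHC class I and cytokines (0.028), disease-associated and all microglia (0.028), and homeostatic microglia and scavenger receptors (0.047). The covariate largely follows genotype here too, and it was chosen after results were seen. Fv1 was called in no fit that left out a library, Dusp1, Egr1 and Fosb in 1 and Cd74 in 2. In all 280 genes were called, 257 higher and 23 lower (voom 250), all without overlap against 18.6% of tested genes and 10% by chance. The count was 166, 159 and 173 without wildtype replicates 1, 2 and 3.

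The genes called in both 5xFAD groups against wildtype numbered 148 higher and 11 lower in prefrontal cortex (3.34 and 0.0207 expected of independent lists, 0 and 0 in simulated unchanged groups) and 256 and 17 in hippocampus (10.8 and 0.0933 expected, 0 and 0.01 simulated). Part of the excess may come from the shared controls. The simulated groups held no changed genes, so their counts cannot show how large that part is. Between tissues, the EV group shared 139 higher (3.53 expected) and 8 lower genes (0.0268 expected). To ask whether EV moved genes against the genotype effect, the covariance across genes of the genotype effect and the EV effect, which share the 5xFAD PBS libraries, was set beside its simulated value. In hippocampus it was -0.0470 against -0.0175 simulated, an excess of -0.0294 (-0.0438 to -0.00638 when a library was left out), and in prefrontal cortex -0.0101 against -0.0142, an excess of 0.00417 (0.00088 to 0.0103). These ranges are not confidence intervals. In both tissues the jackknife standard error, given further below, was larger than the excess, so neither value can be told from no excess. The correlations were -0.594 and -0.228, and genes are not independent replicates. With the genotype effect taken from the other tissue, which shares no library, the covariance was -0.00767 in hippocampus and -0.00219 in prefrontal cortex. Yet 5xFAD PBS libraries with the same number deviated together across tissues for replicates 1 and 2 (correlations of 0.416 and 0.537), though not 3 (-0.00921). If they come from the same mice, shared deviations alone could give a negative covariance. The mean of the 238 genes that rose in prefrontal cortex, read in hippocampus and less the wildtype mean, was 1.23 ± 0.284 with EV and 1.39 ± 0.0800 with PBS (exact permutation p = 0.4). That of the 521 hippocampal genes, read in prefrontal cortex, was 0.600 ± 0.0440 and 0.647 ± 0.0426 (exact permutation p = 0.3). The smallest p that 3 against 3 libraries allow is 0.1.

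Gene Ontology terms gave 186 called of 3272 in prefrontal cortex (153 higher, 33 lower) and 346 of 3319 in hippocampus (214 and 132) for 5xFAD PBS against wildtype. Defense response (8 of 36 and 19 of 37 genes higher), immune response (26 of 112 and 43 of 113, with 1 lower in hippocampus) and presentation of exogenous peptides by MHC class II (7 of 14 and 12 of 15) led in both tissues. For EV against PBS, 68 terms were called in prefrontal cortex (33 and 35), led by structural constituent of ribosome (148 genes, median -0.10) and cellular response to interferon-beta (26 genes, -0.13). In hippocampus 348 were called (209 and 139), led by integral component of postsynaptic density membrane (69 genes, 0.19) and structural constituent of ribosome (148 genes, -0.22). With the trend over gene length removed, 3 and 162 terms were called in all. These totals do not show which of the terms above remained. For EV against wildtype the counts were 219 (141 and 78) and 197 (175 and 22). With an estimated correlation 0 terms passed in any comparison, the lowest adjusted p being 0.29, for 5xFAD PBS against wildtype in prefrontal cortex.

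**Figure D3:**
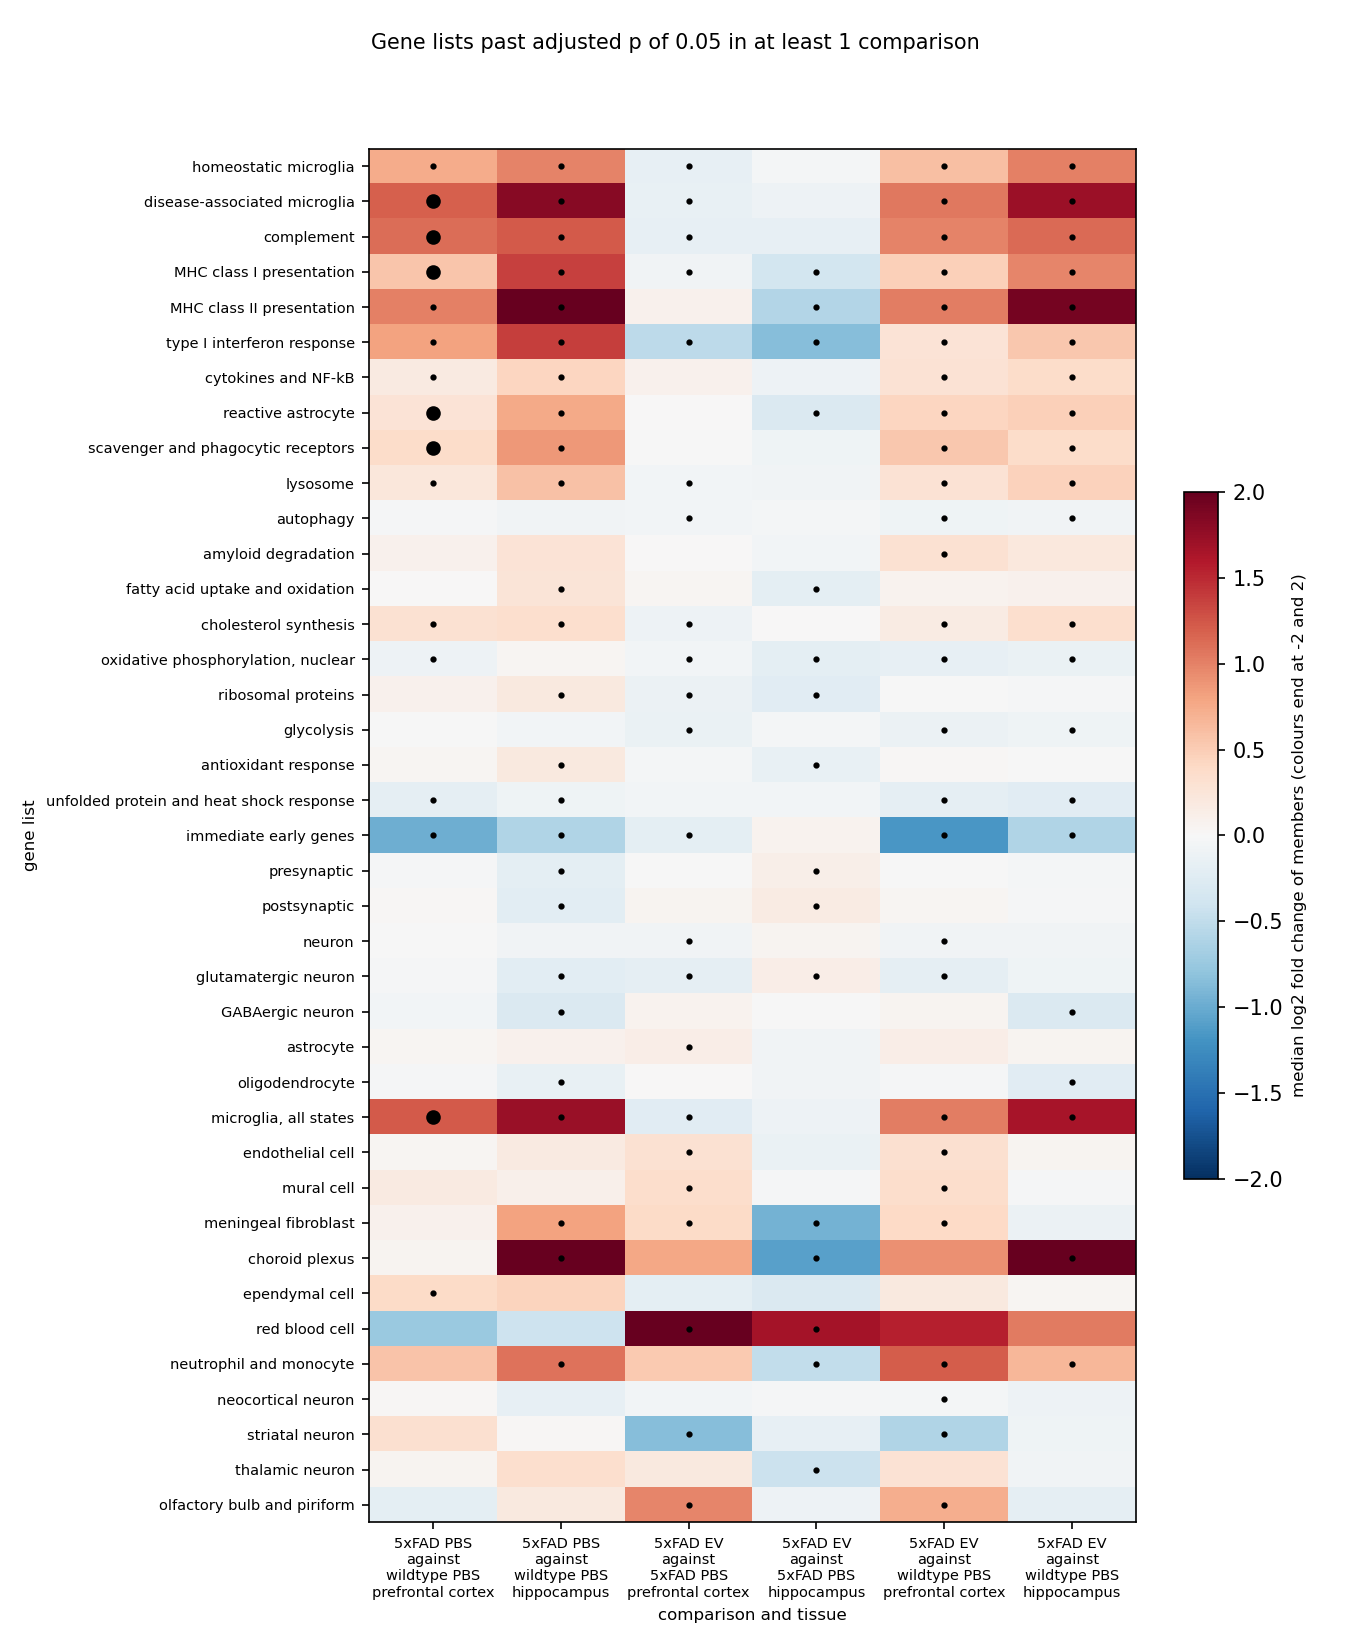
Median log2 fold change of the members of each gene list that passed camera in at least 1 comparison (colour), for 3 comparisons in both tissues. A dot marks an adjusted p under 0.05 with the preset correlation and a large dot one that also passed with an estimated correlation. Large dots occur in the first column alone, for 6 lists of 5xFAD PBS against wildtype PBS in prefrontal cortex.

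Hippocampus and prefrontal cortex of wildtype mice differed in 2156 of 13574 genes, 1184 higher and 972 lower in hippocampus. C1ql2, a secreted synaptic protein of dentate granule cells (5.92, SE 0.12, adjusted p = 7.8e-15), Lct (3.58), Olfml2b (2.83) and Pkp2 (2.57) were higher in hippocampus. Higher in prefrontal cortex were Abi3bp (-3.28, SE 0.21, adjusted p = 3.6e-08), Hs3st2 (-2.04), Medag (-1.98), the transcription factor Meis2 (-1.84) and Tiam2 (-1.38). Hippocampal neuron markers rose with 11 of 14 called (median 2.10, adjusted p = 0.0022 with an estimated correlation), the single list of 14 called (6 higher, 8 lower) that passed in both ways. Striatal (-1.996, adjusted p = 0.41 with an estimated correlation), olfactory (-1.80, 0.36 likewise) and neocortical neuron markers (-0.86, 0.51 likewise) were lower, and ependymal (1.86, 0.41 likewise) and oligodendrocyte markers (0.69, 0.36 likewise) higher in hippocampus.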

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

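Camera at both correlations and median-of-ratios scaling were fixed as methods before the data were examined. The other tests in this part were chosen after results were seen. The comparisons they bear on were fixed before the data were examined. A difference between the tissues drew attention to 8 values. The genotype effect differed between tissues for 24 gene lists, with medians of 3.52 for choroid plexus, 0.77 for MHC class I and 0.43 for disease-associated microglia. The EV effect differed for 20 lists, with medians of -1.29 for meningeal fibroblasts, -1.93 for choroid plexus and 0.31 for glutamatergic neurons. The choroid plexus value for EV was -1.09 without EV prefrontal replicate 3 and -0.90 without EV hippocampus replicate 3, and the glutamatergic value was 0.15 without EV prefrontal replicate 3, so these sizes rest in part on single libraries. None of these differences passed with an estimated correlation between genes.

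Choroid plexus transcripts in 5xFAD hippocampus may reflect how much of that tissue was taken with each block. A single factor per library accounted for 96.2% of the variation of the 13 markers over the 6 5xFAD hippocampus libraries. Markers of 1 tissue could share such a factor whether its amount or its expression differed, so this value cannot tell the 2 apart. A genotype effect on the choroid plexus remains open: 1 of the 6 libraries, EV replicate 3, had Ttr under 2 times the highest wildtype library. Scaling does not account for it, as the median of the markers was 3.60 after median-of-ratios scaling against 3.64 before.

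Cerebellar transcripts in 5xFAD EV prefrontal cortex replicate 3 are likely cerebellar tissue or RNA in that library. Of 25 listed cerebellar genes, 20 lay above 2 times the highest other prefrontal library, with Pcp2 at 178 and Cbln3 at 143 FPKM. A treatment effect does not account for them, as 1 of the 3 EV libraries carried them.

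The lower interferon list with EV could come from the spread between libraries, from fewer microglia, from a trend over gene length or from the vesicles. The list mean differed by -0.49 in prefrontal cortex (exact permutation p = 0.1, the smallest possible) and -0.75 in hippocampus (exact permutation p = 0.2). Among wildtype libraries alone its SD was 0.496 in prefrontal cortex and 0.344 in hippocampus. Relative to microglial markers, the list mean differed by -0.27 in prefrontal cortex (exact permutation p = 0.3) and -0.63 in hippocampus (exact permutation p = 0.2), which cannot tell these apart. With the length trend of each library removed the medians were -0.52 and -0.74, so gene length does not account for it.

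Regrouping the 6 libraries of a comparison in all 10 ways is too few for a share under 0.05. In prefrontal cortex, 5xFAD PBS against wildtype had 256 genes against at most 0 in other splits (1 split with as many), 16 lists against 23 (8 splits) and 186 terms against 331 (5 splits). EV against PBS had 0 genes against 0 (10 splits), 22 lists against 15 (1) and 68 terms against 78 (3). EV against wildtype had 198 genes against 2 (1), 27 lists against 24 (1) and 219 terms against 164 (1). Hippocampus had 611 genes against 0 (1), 25 lists against 22 (1) and 346 terms against 326 (1) for 5xFAD PBS against wildtype. EV against PBS had 0 genes against 192 (10), 16 lists against 25 (7) and 348 terms against 339 (1). EV against wildtype had 280 genes against 1 (1), 21 lists against 23 (4) and 197 terms against 189 (1). The split with 192 genes set PBS 1 with EV 1 and EV 2 against PBS 2, PBS 3 and EV 3, which points to a structure of the samples other than treatment. Slopes over gene length were above 0 on 1 side (0.0358, 0.0566 and 0.0888) and below 0 on the other (-0.166, -0.0255 and -0.0592), and whether that trend underlies the split was not tested. Hippocampus against prefrontal cortex in wildtype had 2156 genes against 0 (1 of 10). For differences between tissues, all 100 splits had at least the 0 genes of the real grouping, with at most 909 for genotype and 3 for EV. The split with 909 kept the true groups in hippocampus and mixed them in prefrontal cortex, so that it holds the genotype effect itself.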

How the results depend on the processing

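The voom, gene length and choroid plexus alternatives, and the fits without a library that held transcripts of another tissue, were chosen after results were seen. Leaving out each library in turn, for the results counted here, was fixed in advance. Of 296 alternatives for 23 results, 244 stayed and 52 moved, with counts held to 1.5 times. The 15 and 16 alternatives for the excess covariance were held instead to its jackknife standard error (0.00815 in prefrontal cortex, 0.0315 in hippocampus), which is larger than the value itself (0.00417 and -0.0294). All 31 stayed within that, though several moved by over 1.5 times. For the 52 the cause was not tested, except where the alternative itself drops libraries or tests another way. Library quality weights gave 480, 3 and 764 genes in prefrontal cortex (5xFAD PBS against wildtype, EV against PBS, EV against wildtype) and 3785 and 4665 in hippocampus against wildtype, where the weights did not converge (39.1 for wildtype replicate 2). An estimated correlation left 6 lists for 5xFAD PBS against wildtype in prefrontal cortex and 0 in the other 5 comparisons of groups within a tissue, and 0 terms in all 6. fry called 0 lists for EV against PBS in both tissues, and 15 and 12 for EV against wildtype. An unadjusted p under 0.05 with over 1.5-fold change gave 78 and 371 genes in prefrontal cortex and 152 and 540 in hippocampus for EV against PBS and EV against wildtype. EV against wildtype in prefrontal cortex had 125 genes after quantile normalization and 118 with only its 6 libraries. All 18 libraries in the fit gave 1028 and 432 genes in hippocampus for 5xFAD PBS and EV against wildtype. Removing the length trend gave 948 genes for 5xFAD PBS against wildtype in hippocampus, and 3 and 162 terms for EV against PBS. The choroid plexus covariate gave 278 genes.

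Leaving out 1 library gave 142 to 218 genes (5xFAD PBS against wildtype), 0 to 1 (EV against PBS) and 89 to 229 (EV against wildtype) in prefrontal cortex, and 320 to 446, 0 to 1 and 159 to 278 in hippocampus. Lists ranged over 16 to 19, 14 to 24 and 21 to 32 in prefrontal cortex and 25 to 28, 13 to 23 and 18 to 25 in hippocampus. The excess covariance ranged from 0.00088 to 0.0103 in prefrontal cortex and -0.0438 to -0.00638 in hippocampus, and was -0.0500 in hippocampus with the choroid plexus covariate. Hippocampus against prefrontal cortex in wildtype ranged from 1476 to 2178 genes, and the tissue differences stayed at 0.

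With the replicate number as a block, the counts were 218, 0 and 204 genes, 17, 22 and 27 lists and 186, 95 and 210 terms in prefrontal cortex. They were 503, 0 and 236 genes, 24, 15 and 21 lists and 349, 368 and 183 terms in hippocampus, and 0, 0 and 2398 for the tissue contrasts, so that the block moved no count by over 1.5 times. The block ended 3 of the list calls: unfolded protein (5xFAD PBS against wildtype) and reactive astrocytes (EV against PBS) in hippocampus, and olfactory markers (EV against wildtype) in prefrontal cortex. Of 18 pairs sharing a number within a tissue, 8 correlated over 0.1 (-0.409 to 0.509), and 7 libraries correlated best with their own number. Across tissues, 4 of 9 pairs of the same group and number correlated over 0.1 (-0.293 to 0.537), and 4 correlated best with their own number. For 5xFAD PBS against wildtype in prefrontal cortex, whose 3 pairs were all over 0.1, 206 of the 256 genes were also called with the block, and 215 genes were called with the length trend removed as well. Of the genes and lists named there, the block changed no call but those given with it.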

Other observations

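Tests in this part were chosen after results were seen, and its genes were chosen after values were seen. Wdfy1 was at 1.12 to 1.35 FPKM in all wildtype libraries and 3.78 to 4.89 in all 5xFAD libraries of both tissues. Elk1 was at 17.7 to 19.3 in wildtype prefrontal cortex and 25.8 to 27.6 in wildtype hippocampus, at 20.3, 17.6 and 23.9 in 5xFAD PBS prefrontal replicate 3, EV prefrontal replicate 3 and EV hippocampus replicate 3, and at 9.31 to 11.5 in the other 5xFAD libraries.

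Ptn was at 122 in prefrontal cortex and 98.9 in hippocampus of 5xFAD PBS replicate 1, and at 163.5 or more in all other libraries. Liver transcripts were highest in wildtype hippocampus replicate 3, with Alb at 13.2 FPKM against 0.446 to 5.07 in the other hippocampus libraries and Mup3 at 8.58 against 0.403 to 4.27. The kidney gene Kap was at 31.7 there and at most 3.26 in any other library.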
